A study of Xenopus laevis with 16 samples.

How the data were processed

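Pancreas RNA of Xenopus laevis tadpoles and adult frogs was labelled with Cy3 and hybridised with a Cy5-labelled universal reference RNA on 16 Agilent arrays, per the labels' protocols. The dyes were not swapped. Tadpoles had 1 week in 1 mM methimazole before 100 nM T3 was added. Each tadpole sample is a pool of several organs, so its spread is that between pools. Tadpole organs were kept in a storage reagent before extraction, while adult organs went straight into the extraction reagent, per the labels. The arrays lie on 4 slides, and position on the slide went with the group for tadpole samples.

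The deposited scanner files hold the mean and background intensity of each spot in both channels, processed intensities and a log10 ratio of Cy5 over Cy3. They were made with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited table of values holds a processed number for each probe and array, on a scale that is not stated. Its deviations from the probe means followed those of log10 of sample over reference, with a slope of 0.998 and a correlation per array of 0.986 to 0.999. It was therefore taken as log10 with the sample on top, while its centring stays unknown. Its column medians were 2.11, 2.11, 2.08 and 2.04 for the control arrays, 2.11, 2.11 and 2.1 at 12 h, 2.11, 2.11 and 2.1 at 24 h, 2.11, 2.09 and 2.12 at 48 h and 2.04, 2.05 and 2.04 in adult. The median Cy3 background was 35 to 39 on slides 1 to 3 and 48 to 51 on slide 4.

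Mean intensities were background corrected with normexp at an offset of 50 and normalized within each array by loess, with control and flagged spots at weight 0. The log2 ratio of Cy3 over Cy5 was then taken. The tools were limma 3.58.1, R 4.3.3 and data.table (version 1.17.8). Of 33206 probes, the 22001 well above background in Cy3 on at least 3 of the 16 arrays were tested. Control replicates 1 and 4 are 2 arrays of 1 RNA pool and were averaged, which left 15 samples, 3 per group. All 5 groups were fitted in 1 model with lmFit and eBayes. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of the 7 contrasts, at 0.05. A probe not well above background on any array of a group has only a bound there, given as "at least". Such bounds come from values per channel after loess and Aquantile and are open to dye bias.

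Probes were named through accession, gene ID, symbol or synonym in a RefSeq gene table of the Xenopus laevis J strain assembly. This named 11479 of 33206 probes, others keep the file's name, and 11230 probes carried a symbol that was not a placeholder, for 9712 genes. Clones without a gene symbol, 21976 probes, were counted but not named. The suffixes .L and .S mark homeologs, the gene copies of the 2 subgenomes of this species. For a gene with several probes the one with the highest mean intensity was used. Probes were called in opposite directions for 4 genes at 12 h, 7 at 24 h, 45 at 48 h and 69 in adult, of 884 genes with more than 1 tested probe. In these comparisons 353, 354, 653 and 645 of the 884 genes had a called probe. For 287, 273, 416 and 447 genes some probes were called and others were not.

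The rule for named genes was fixed before the data were examined. It takes the 6 largest rises and the 6 largest falls in each comparison with control among called genes that kept their sign in every sample. It adds up to 4 members of each gene list with the smallest adjusted p. It also adds 15 genes of hormone response, digestion and islets whatever their values, of which pdx1 was not matched to a probe. Some genes that the rule takes are not reported here.

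The 29 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. With the estimated correlation 0 of 29 lists were called in each of the 7 contrasts. At an unadjusted p under 0.05 there were then 2 lists at 12 h, 5 at 24 h, 5 at 48 h, 1 in adult, 1 between adult and 48 h and 2 in each contrast between times. Each list was also set beside other probes with like brightness in both channels. Only the 1 probe used for each list gene was left out of these. They can hold other probes of the list's genes and unnamed clones of the same transcripts. For a list of very bright genes the comparison may thus partly set the list beside itself, or beside transcripts of the same kind. This comparison and the values of each channel by itself at digestive enzyme probes were added after the data were examined. Values from a channel alone were quantile normalized, which gives every array the same distribution. That step can hide a shared change of the brightest probes, where digestive enzymes lie.

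Replicates 1 to 3 of the tadpole groups shared slides 1 to 3, which pairs the samples. Deviations from the group means correlated at -0.265 to 0.203 (median -0.0338, 18 pairs) within slides and at -0.267 to 0.316 (median 0.0147, 36 pairs) between slides. The consensus correlation within slides was -0.0979. Adult samples share only a number with the others.

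The fit was tested on simulated data over 22001 probes with known changes of 0.5, 1 and 2 on the log2 scale. It recovered 46.3%, 89.6% and 100.0% of the changed probes at 12 h, 43.3%, 83.6% and 97% at 24 h, 52.2%, 92.5% and 98.5% at 48 h and 58.2%, 94% and 100.0% in adult. The false calls numbered 5, 9, 12 and 9, which were 3.1%, 5.7%, 6.9% and 5.1% of the simulated calls. In each simulated comparison only 67, 67 and 66 probes were changed, by 0.5, 1 and 2. The data called far more probes, 4544 at 12 h and 10480 at 48 h. The simulated recovery and numbers of false calls need not hold there. Alternatives were other background corrections and normalizations, the processed signals, the value table, Cy3 alone, other filters, variance models and blocks, and each replicate left out. The number of arrays limits the precision.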

Results

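Gene expression was measured in the pancreas of the frog Xenopus laevis on 16 two-colour oligonucleotide arrays. Premetamorphic tadpoles were kept in 1 mM methimazole, which blocks the making of thyroid hormone, and then given 100 nM T3, the active thyroid hormone, for 12, 24 or 48 h in the same bath. Control tadpoles had methimazole without T3 and were collected together with the 48 h animals, so no control was taken at 12 h or 24 h. The 5th group was the pancreas of untreated adult female frogs. Each tadpole sample pooled the organs of several animals, each group had 3 samples, and control pool 1 was hybridised on 2 arrays, whose mean counted as 1 sample. Every array carried a sample in Cy3 and a universal Xenopus laevis reference RNA in Cy5, so each value is the log2 ratio of sample to reference and each change is a difference of group means of such ratios. Slides 1 to 3 each held 1 sample of every tadpole group, and slide 4 held the 3 adult samples and the repeat array of control pool 1. The share of probes well above background in the sample channel lay from 53.3% to 67.5% on slides 1 to 3 and from 45.7% to 46.7% on slide 4. No probe was saturated in either channel. Before normalization the 100 brightest probes of an array held 52.8% to 56.3% of the Cy3 signal in control. Their share was 45.6% to 50.9% at 12 h and 46.7% to 51.3% at 24 h. At 48 h it was 39.4% to 40.4%, and in adult 62.4% to 65.3%. The 100 brightest probes were taken on each array by itself, and the share of digestive enzymes in the signal was not computed. The 3 samples per group limit the precision.

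Folds are followed in parentheses by the log2 change ± its standard error, with n = 3 samples per group, and calls are at an adjusted p under 0.05 (limma, two-sided, 22001 probes). The 2 control arrays of the same RNA correlated at r = 0.99 across probes, with an SD of their difference of 0.162, against 0.231 and 0.234 between control pools. In a principal component analysis of the 15 samples the first component held 59.4% of the variance and set the adult samples, at -100.5 to -97.7, apart from the tadpole samples, at -8.08 to 43.7. The second component, with 19.8%, ran from control, at 35.1 to 38.8, through 12 h of T3, at 21.1 to 24.3, and 24 h, at -3.63 to 8.26, to 48 h, at -49.5 to -44.9.

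The 12 h samples addressed which genes moved first under T3. Known direct targets of the hormone receptor were higher: the receptor gene thrb 2.38-fold (1.25 ± 0.097, adjusted p = 1.83e-05) and the zinc finger factor klf9.L 1.94-fold (0.95 ± 0.17). The nuclear factor I genes nfix.L 4.89-fold (2.29 ± 0.23) and nfib.L 7.04-fold (2.81 ± 0.17) and the arginine methyltransferase prmt1.S 3.54-fold (1.82 ± 0.20) were higher too. The leucine zipper gene thibz.L and the stromelysin gene mmp11.L were not well above background in control and rose at least 1.83-fold and at least 3.48-fold. In the direct thyroid hormone response list, 10 of 20 measured genes rose and 1 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.69 (camera adjusted p = 0.000104, and adjusted p = 0.172 with an estimated correlation). The 1 member that fell was dio3.L, the deiodinase that inactivates the hormone, by 1.81-fold (-0.86 ± 0.11). The largest rises of named genes were those of cyp51a1.L 8.13-fold (3.02 ± 0.38, adjusted p = 0.000278), the sterol demethylase, and of slc16a6.L 7.79-fold (2.96 ± 0.25), a monocarboxylate transporter. Next came thdl20 7.28-fold (2.86 ± 0.35), thdl18.S 7.04-fold (2.82 ± 0.37), nfib.L and g6pc1.2.L 6.39-fold (2.68 ± 0.38). The names thdl20 and thdl18 stand, in the array's annotation, for transcripts lowered by the hormone. The largest falls were those of nfil3.L 4.16-fold (-2.06 ± 0.32), a leucine zipper repressor, sult1b1.S 3.31-fold (-1.73 ± 0.21), a sulfotransferase, and npr2.L 3.26-fold (-1.70 ± 0.33), a guanylyl cyclase. Then came plk1.S 3.02-fold (-1.59 ± 0.19), a mitotic kinase, map1lc3a.L 3.01-fold (-1.59 ± 0.42), an autophagy protein, and slc7a3.L 2.9-fold (-1.53 ± 0.40), an amino acid transporter.

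Genes of sterol synthesis rose at 12 h: in the sterol and fatty acid synthesis list, 16 of 28 measured genes rose and 0 fell (17 and 0 adjusted over the list alone). Its median was 0.61 (camera adjusted p = 9.03e-07, and adjusted p = 0.531 with an estimated correlation). Examples were cyp51a1.S 5.96-fold (2.58 ± 0.38) and acly.L 2.79-fold (1.48 ± 0.17). The median lay from 0.25 to 1.2 within the 3 slides. The proteasome list had 25 of 46 measured genes higher and 0 lower (28 and 0 adjusted over the list alone, camera adjusted p = 1.68e-07, and adjusted p = 0.172 with an estimated correlation). Examples were psmd10.S 2.59-fold (1.38 ± 0.19) and psmc6.S 1.77-fold (0.82 ± 0.091). Of the amino acid synthesis and tRNA charging list, 14 of 31 measured genes rose and 3 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.00902, and adjusted p = 0.697 with an estimated correlation). Here the serine synthesis enzyme psat1.L 5.36-fold (2.42 ± 0.33) and the tRNA synthetases mars1.L 2.57-fold (1.36 ± 0.28) and tars1.L 2.55-fold (1.35 ± 0.24) were higher. The cystathionine synthase cbs.L 1.89-fold (-0.92 ± 0.19) was lower. The immediate early and heat shock list had 13 of 30 measured genes higher and 2 lower (15 and 2 adjusted over the list alone, camera adjusted p = 0.00233, and adjusted p = 0.531 with an estimated correlation). Examples were jund.S 3.35-fold (1.74 ± 0.28), hspd1.S 3.12-fold (1.64 ± 0.26) and hsph1.L 2.86-fold (1.52 ± 0.20). In the cell cycle list 36 of 90 measured genes rose and 13 fell (37 and 15 adjusted over the list alone, camera adjusted p = 0.00902, and adjusted p = 0.697 with an estimated correlation). Its median within slides 1, 2 and 3 was 0.14, 0.32 and -0.017. Of its members, the replication genes mcm3.L 4.11-fold (2.04 ± 0.21) and mcm10.L 2.31-fold (1.21 ± 0.12) were higher. The mitotic genes plk1.S and cdc20.L 2.54-fold (-1.35 ± 0.14) were lower. Replication and mitosis were not tested as lists of their own. In the endoplasmic reticulum list 17 of 77 measured genes rose and 5 fell (25 and 6 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.697 with an estimated correlation). Among them were the chaperone hyou1.S 3.41-fold (1.77 ± 0.34) up and the secretory regulator xbp1.L 2.04-fold (-1.03 ± 0.19) down.

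Several lists moved down at 12 h. Ribosomal protein genes had 0 of 61 measured genes higher and 28 lower (0 and 40 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 1.68e-07, and adjusted p = 0.531 with an estimated correlation), while probes of like brightness in both channels had a median of -0.39. The collagens and matrix list had 0 of 31 measured genes higher and 14 lower (0 and 15 adjusted over the list alone, camera adjusted p = 0.00376, and adjusted p = 0.531 with an estimated correlation; like-brightness median -0.19). Examples were col3a1.S 1.87-fold (-0.90 ± 0.18) and sparc.L 1.8-fold (-0.85 ± 0.11). Among leukocyte markers, 0 of 25 measured genes rose and 9 fell (0 and 11 adjusted over the list alone, camera adjusted p = 0.000867, and adjusted p = 0.531 with an estimated correlation; like-brightness median -0.11). An example was the myeloperoxidase mpo.L 2.56-fold (-1.36 ± 0.30). The acinar regulators and secretory markers list had 0 of 10 measured genes higher and 4 lower (1 and 6 adjusted over the list alone, camera adjusted p = 0.0206, and adjusted p = 0.531 with an estimated correlation). Its median was -0.38 against -0.40 for probes of like brightness. The endocrine pancreas list had 0 of 22 measured genes higher and 4 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.0163, and adjusted p = 0.697 with an estimated correlation). Its median was -0.33 against -0.060. The digestive enzymes list had 0 of 20 measured genes higher and 4 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0245, and adjusted p = 0.667 with an estimated correlation). Its median was -0.47 against -0.46 for probes of like brightness, and came to 0.0040 from the sample channel alone. Quantile normalization of that channel can hide a shared fall of the brightest probes. Before normalization their share of its signal was 45.6% to 50.9% at 12 h, against 52.8% to 56.3% in control. Also called lower were the skeletal muscle (0 up and 5 down of 27), neural and glial (0 up and 8 down of 26), smooth muscle and stroma (0 up and 5 down of 19) and lysosome and autophagy (2 up and 13 down of 49) lists. Adjusted over the list alone these counts were 0 and 5, 0 and 15, 0 and 5, and 3 and 16. Their medians were -0.25, -0.30, -0.25 and -0.27, against -0.23, -0.23, -0.16 and -0.071 for probes of like brightness. The camera adjusted p was 0.0094, 0.0032, 0.0163 and 0.0369, and with an estimated correlation 0.697, 0.667, 0.697 and 0.697. The duct and progenitor regulators sox9.L 1.87-fold (-0.91 ± 0.15) and sox9.S 1.55-fold (-0.63 ± 0.15) fell. The factor sox4.L 2.68-fold (1.42 ± 0.19) rose. Insulin (ins.S, -0.42 ± 0.16, adjusted p = 0.084) and glucagon (gcg.L, -0.13 ± 0.19, adjusted p = 0.703) did not pass the test. Nor did amylase (amy2a.L, -0.55 ± 0.24, adjusted p = 0.12), trypsin (prss1.L, 0.052 ± 0.077, adjusted p = 0.708) or the acinar factor ptf1a.L (0.28 ± 0.11, adjusted p = 0.092).

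In all, 4544 probes differed from control at 12 h, 2062 higher and 2482 lower, and 528 by at least 2-fold (404 higher, 124 lower). With the slide as a block the count was 4499 from the tadpole samples alone and 3989 from all 16 arrays. In the tadpole block ins.S at 12 h (adjusted p = 0.0274) and ptf1a.L at 12 h (adjusted p = 0.0498) passed the test, and in the 16-array block neither did (adjusted p = 0.0962 and 0.107). On slides 1, 2 and 3 taken alone 99.5%, 99.9% and 99.7% of the called probes had the sign of the fit. The same samples gave the calls, so this agreement was largely fixed in advance and is no independent support. The count fell to 2821 without control replicate 2, to 2839 without 12 h replicate 2 and to 1558 (89.8% higher, against 45.4%) when arrays were centred on the median in place of loess. The share higher was 58% with the scanner software's processed signals and 57.9% with the deposited value table. The camera call was lost with median centring for the cell cycle list (adjusted p = 0.27). It was lost with the processed signals for the endoplasmic reticulum (adjusted p = 0.105) and amino acid synthesis and tRNA charging (adjusted p = 0.0627) lists, and from the sample channel alone for digestive enzymes (adjusted p = 0.759). For digestive enzymes the quantile normalization of that channel can itself remove the call. The calls of skeletal muscle (adjusted p = 0.196 and 0.371) and of neural and glial genes (adjusted p = 0.22 and 0.371) were lost both with the processed signals and from the sample channel alone. With median centring the calls of skeletal muscle (adjusted p = 0.174) and of lysosome and autophagy genes (adjusted p = 0.133) were lost, and their medians turned to 0.046 and 0.033, where the median of all probes was 0.0077.

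At 24 h direct hormone targets were again higher than control. The matrix protease mmp11.L rose at least 14-fold and thibz.L at least 2.74-fold, both again not well above background in control. Among measured targets were nfix.L 13.8-fold (3.79 ± 0.23, adjusted p = 7.42e-07), nfib.L 10.9-fold (3.44 ± 0.17), thrb 3.37-fold (1.75 ± 0.097), sox4.L 6.12-fold (2.61 ± 0.19) and klf9.L 2.8-fold (1.49 ± 0.17). The deiodinase gene dio3.L fell 2.69-fold (-1.43 ± 0.11). In the direct thyroid hormone response list 13 of 20 measured genes rose and 1 fell (13 and 1 adjusted over the list alone). Its median was 1.21 (camera adjusted p = 1.78e-06, and adjusted p = 0.0716 with an estimated correlation). Other large rises were those of arg2.S 9.25-fold (3.21 ± 0.34), a mitochondrial arginase, bcl6.S 7.94-fold (2.99 ± 0.26), a transcriptional repressor, and paaf1.S 8.45-fold (3.08 ± 0.23), a proteasome-binding factor. The largest falls were nfil3.L 8.12-fold (-3.02 ± 0.32), trim2.S 5.66-fold (-2.50 ± 0.22) and palmd.L 5.04-fold (-2.33 ± 0.16). Next were sh3bp4.S 4.99-fold (-2.32 ± 0.17), fbp1.L 4.77-fold (-2.25 ± 0.30), an enzyme of gluconeogenesis, and nr1d1.L 4.65-fold (-2.22 ± 0.23), a clock repressor.

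Acinar regulators were lower at 24 h: 0 of 10 measured genes rose and 7 fell (0 and 8 adjusted over the list alone, camera adjusted p = 0.000738, and adjusted p = 0.226 with an estimated correlation; median -0.60, like-brightness median -0.33). Examples were xbp1.L 2.74-fold (-1.45 ± 0.19) and the nuclear receptor nr5a2.S 2.24-fold (-1.16 ± 0.18). The digestive enzymes list was not called, with 2 of 20 measured genes higher and 5 lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.266). Within it cela1.2.L 4.31-fold (2.11 ± 0.35), an elastase, was higher and cpa1.S 1.49-fold (-0.58 ± 0.12), a carboxypeptidase, lower. Cell cycle genes had 37 of 90 measured genes higher and 7 lower (40 and 11 adjusted over the list alone, camera adjusted p = 0.000793, and adjusted p = 0.774 with an estimated correlation). Their median within slides 1, 2 and 3 was 0.48, 0.26 and -0.024. Examples were mcm7.L 2.93-fold (1.55 ± 0.20), mcm4.L 2.97-fold (1.57 ± 0.20) and mcm3.L (1.66 ± 0.21). The immediate early and heat shock list had 16 of 30 measured genes higher and 1 lower (17 and 2 adjusted over the list alone, camera adjusted p = 9.17e-06, and adjusted p = 0.226 with an estimated correlation). Examples were jund.S 5.61-fold (2.49 ± 0.28), jun.L 3.99-fold (2.00 ± 0.25) and btg2.S 3.6-fold (1.85 ± 0.23). The proteasome list had 19 of 46 measured genes higher and 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 1.78e-06, and adjusted p = 0.226 with an estimated correlation). The sterol and fatty acid synthesis list was not called (median 0.078, 5 up and 2 down of 28, camera adjusted p = 0.586).

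Marker lists of other tissues also moved at 24 h, the skeletal muscle, neural and intestine lists by about as much as probes of like brightness. In the skeletal muscle list 0 of 27 measured genes rose and 16 fell (0 and 20 adjusted over the list alone). Its median was -0.53 against -0.50 for probes of like brightness (camera adjusted p = 3.2e-06, and adjusted p = 0.607 with an estimated correlation). In the neural and glial list 1 of 26 measured genes rose and 13 fell (1 and 17 adjusted over the list alone). Its median was -0.36 against -0.40 (camera adjusted p = 0.00335, and adjusted p = 0.774 with an estimated correlation). With the processed signals it turned to 0.022. Intestine markers had 0 of 12 measured genes higher and 6 lower (0 and 11 adjusted over the list alone). Their median was -0.53 against -0.52 (camera adjusted p = 0.0102, and adjusted p = 0.535 with an estimated correlation). Leukocyte markers had 0 of 25 measured genes higher and 7 lower (0 and 7 adjusted over the list alone). Their median was -0.29 against -0.13 (camera adjusted p = 0.0103, and adjusted p = 0.774 with an estimated correlation). Ribosomal proteins were lower (0 up and 6 down of 61; median -0.24 against -0.18; camera adjusted p = 0.0102, and adjusted p = 0.774 with an estimated correlation). So were endocrine genes (0 up and 5 down of 22; median -0.27 against -0.099; camera adjusted p = 0.0169, and adjusted p = 0.774 with an estimated correlation). The medians of the ribosomal and endocrine lists turned to 0.28 and 0.091 when arrays were centred on the median, where the median of all probes was 0.081. Among endocrine genes the beta cell factor nkx6-1.L 2.97-fold (-1.57 ± 0.21) fell. The genes ins.S (-0.37 ± 0.16, adjusted p = 0.121) and gcg.L (-0.050 ± 0.19, adjusted p = 0.889) did not pass the test.

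Against control, 5184 probes differed at 24 h, 2198 higher and 2986 lower, 638 by at least 2-fold (370 higher, 268 lower). The count with the slide as a block was 5126 from the tadpole samples alone and 4604 from all 16 arrays. On slides 1, 2 and 3, 99.9%, 99.5% and 98.9% of the called probes had the sign of the fit. These slides also gave the calls, so that agreement was largely fixed in advance. In the tadpole block ins.S at 24 h passed the test (adjusted p = 0.0399), and in the 16-array block it did not (adjusted p = 0.131). The share higher was 42.4%, but 93.4% with median centring, 57.2% with the processed signals, 57.2% with the value table and 52.4% from the sample channel alone. The camera call was lost with median centring for the cell cycle (adjusted p = 0.128) and ribosomal proteins (adjusted p = 0.512) lists, and with the processed signals for the intestine (adjusted p = 0.0956) and neural and glial (adjusted p = 0.434) lists.

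After 48 h of T3 the pancreas had higher ratios to the reference for cell cycle and hormone response genes and lower ratios for secretory pathway and respiration genes. The digestive enzymes list was lower too, by about as much as probes of like brightness, and its call was lost from the sample channel alone (camera adjusted p = 0.541). Quantile normalization of that channel can hide a shared fall of the brightest probes, so the lost call does not argue against a fall. The matrix proteases and inhibitors list was higher, a call lost with median centring (adjusted p = 0.0771). The largest rises of named genes were those of olfm4.L 47.6-fold (5.57 ± 0.47, adjusted p = 1.02e-06), an olfactomedin called Tiarin in the array's annotation, and nfix.L 43.9-fold (5.46 ± 0.23). They were followed by the elastase cela3b.L 30.1-fold (4.91 ± 0.67), nceh1.S 26.2-fold (4.71 ± 0.25), a cholesterol ester hydrolase, and rfb-a 21.4-fold (4.42 ± 0.46), a riboflavin-binding protein. The gene mmp11.L rose at least 19-fold over a control that was not well above background. The largest fall was that of gatm.L 83.1-fold (-6.38 ± 0.34, adjusted p = 3.44e-08), which makes the precursor of creatine. Next were cdo1.L 21.7-fold (-4.44 ± 0.28), cysteine dioxygenase, and fbp1.L 16.2-fold (-4.02 ± 0.30), fructose bisphosphatase. Further falls were those of agxt.L 15.2-fold (-3.93 ± 0.22), alanine-glyoxylate aminotransferase, trim2.S 14.9-fold (-3.89 ± 0.22) and aldh1l1.L 14.5-fold (-3.86 ± 0.20), a folate enzyme. In the direct thyroid hormone response list 16 of 20 measured genes rose and 1 fell (16 and 2 adjusted over the list alone). Its median was 1.29 (camera adjusted p = 4.51e-05, and adjusted p = 0.216 with an estimated correlation). Its members thrb 2.4-fold (1.26 ± 0.097), klf9.L 2.51-fold (1.33 ± 0.17) and sox4.L 10.6-fold (3.40 ± 0.19) rose. The gene dio3.L fell 2.60-fold (-1.38 ± 0.11) and its homeolog dio3.S rose 1.58-fold (0.66 ± 0.16).

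Digestive enzyme genes were mostly lower at 48 h: 4 of 20 measured genes rose and 12 fell (4 and 12 adjusted over the list alone). Their median was -1.06 (camera adjusted p = 0.0231, and adjusted p = 0.459 with an estimated correlation). The median of probes of like brightness was -0.99, and the list median was -0.034 from the sample channel alone. Quantile normalization of that channel can hide a shared fall of the brightest probes. Before normalization their share of its signal was 39.4% to 40.4% at 48 h, against 52.8% to 56.3% in control. In that channel 15 of the 16 called enzymes kept their sign but 5 changed by over 1. The reference signal changed in the direction opposite to the ratio in 8 of the 16 and in the same direction in the others. Each channel was normalized apart from the ratio, so the channel changes need not add up to it. At ctrc.L the ratio changed by -1.07, Cy3 by -0.0009 and Cy5 by 0.018. The largest fall was that of chymotrypsinogen, ctrb1.L 8.41-fold (-3.07 ± 0.19, adjusted p = 1.05e-07). Others with the smallest adjusted p were amy2b.S 3.12-fold (-1.64 ± 0.16), cel.2.L 2.77-fold (-1.47 ± 0.16) and cpa1.S 2.1-fold (-1.07 ± 0.12). From the sample channel alone ctrb1.L changed by -3.40, amy2b.S by -0.083, cel.2.L by -0.15 and cpa1.S by -0.45. Values near 0 there do not show that an enzyme stayed level, given that normalization. The reference channel changed by -0.64, 0.45, 0.094 and -0.20 at these probes. Of the 4 enzymes of the list that rose, 3 were cela1.2.L 6.88-fold (2.78 ± 0.35), prss1.2.S 19.7-fold (4.30 ± 0.94) and cela3b.L. At prss1.2.S the reference channel changed by 1.86, so the size of its rise is uncertain. Acinar regulators had 0 of 10 measured genes higher and 9 lower (0 and 9 adjusted over the list alone). Their median was -1.10, against -0.89 for probes of like brightness (camera adjusted p = 9.11e-05, and adjusted p = 0.227 with an estimated correlation). Examples were xbp1.L 5.82-fold (-2.54 ± 0.19), pdia2.L 2.32-fold (-1.21 ± 0.12) and aqp12a.S 2.8-fold (-1.48 ± 0.17). The acinar factor ptf1a.L was at -0.37 ± 0.11 on the log2 scale (adjusted p = 0.0135) and the amylase amy2a.L at -0.73 ± 0.24 (adjusted p = 0.021). From the sample channel alone amy2a.L came to 0.14 and ptf1a.L to 0.13, and with median centring ptf1a.L came to 0.45. Islet hormones fell: ins.S 1.97-fold (-0.98 ± 0.16), gcg.L 1.85-fold (-0.89 ± 0.19), and ins.L 3.26-fold (-1.71 ± 0.21), whose probe carries the name igf2 in the array's annotation. The endocrine pancreas list had 0 of 22 measured genes higher and 8 lower (0 and 8 adjusted over the list alone). Its median was -0.31 against -0.23 for probes of like brightness (camera adjusted p = 0.0231, and adjusted p = 0.576 with an estimated correlation). It turned to 0.33 with median centring, where the median of all probes was 0.141. The progenitor factor sox9 fell in both homeologs (-1.35 ± 0.15 and -1.01 ± 0.15).

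Genes of the secretory pathway and of respiration fell together. The endoplasmic reticulum list had 3 of 77 measured genes higher and 44 lower (3 and 45 adjusted over the list alone). Its median was -0.68, against -0.28 for probes of like brightness (camera adjusted p = 2.57e-06, and adjusted p = 0.382 with an estimated correlation). Examples were kdelr3.L 3.66-fold (-1.87 ± 0.17) and dnajb11.S 2.64-fold (-1.40 ± 0.12). The signal peptidase subunit sec11a.L 2.72-fold (1.44 ± 0.10) rose. In the oxidative phosphorylation list 1 of 46 measured genes rose and 34 fell (1 and 35 adjusted over the list alone). Its median was -0.67 against 0.0016 (camera adjusted p = 8.61e-09, and adjusted p = 0.227 with an estimated correlation). Examples were ndufs4.S 2.19-fold (-1.13 ± 0.079) and cyc1.S 2.48-fold (-1.31 ± 0.13). Ribosomal proteins had 0 of 61 measured genes higher and 46 lower (0 and 53 adjusted over the list alone). Their median was -0.58 against -0.43 (camera adjusted p = 2.96e-09, and adjusted p = 0.382 with an estimated correlation). An example was rps3.L 3.1-fold (-1.63 ± 0.16). Of the amino acid synthesis and tRNA charging list, 2 of 31 measured genes rose and 15 fell (2 and 15 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.493 with an estimated correlation). Examples were cbs.S 11.4-fold (-3.51 ± 0.17) and gars1.L 3.09-fold (-1.63 ± 0.20). The list's median of -0.35, against -0.19 for probes of like brightness, turned to 0.085 with median centring, where the median of all probes was 0.141. In the sterol and fatty acid synthesis list, which was not called, 6 up and 10 down of 28 measured genes passed the test (camera adjusted p = 0.406).

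Cell cycle genes rose together at 48 h: 69 of 90 measured genes rose and 2 fell (74 and 2 adjusted over the list alone). Their median was 0.77 against 0.051 for probes of like brightness (camera adjusted p = 2.03e-10, and adjusted p = 0.382 with an estimated correlation). Examples were mcm7.L 4.54-fold (2.18 ± 0.20), the kinetochore gene nuf2.S 2.96-fold (1.57 ± 0.14) and birc5l.L 2.45-fold (1.29 ± 0.12). The list median lay from 0.51 to 0.99 within the 3 slides. The proteasome list had 29 of 46 measured genes higher and 2 lower (30 and 2 adjusted over the list alone, camera adjusted p = 8.92e-05, and adjusted p = 0.282 with an estimated correlation). The lysosome and autophagy list had 27 of 49 measured genes higher and 9 lower (27 and 10 adjusted over the list alone, camera adjusted p = 0.0221, and adjusted p = 0.541 with an estimated correlation). Examples were lgmn.L 4.07-fold (2.03 ± 0.20) and glb1.L 3.63-fold (1.86 ± 0.13). The immediate early and heat shock list had 17 of 30 measured genes higher and 4 lower (18 and 5 adjusted over the list alone, camera adjusted p = 0.0066, and adjusted p = 0.382 with an estimated correlation). Examples were jund.S 7.76-fold (2.96 ± 0.28) and hsph1.L 4.44-fold (2.15 ± 0.20). In the matrix proteases and inhibitors list 16 of 26 measured genes rose and 2 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.00556, and adjusted p = 0.382 with an estimated correlation). Among them were mmp2.S 3.04-fold (1.61 ± 0.12) and fap.L 2.75-fold (1.46 ± 0.14), both up. The apoptosis list was not called (11 up and 5 down of 29; camera adjusted p = 0.36). Examples were bax.S 2.28-fold (1.19 ± 0.080) and casp1 2.77-fold (1.47 ± 0.17) higher and casp8.L 1.91-fold (-0.93 ± 0.096) lower. Collagens and matrix genes went both ways (15 up and 7 down of 31; camera adjusted p = 0.306). Examples were serpinh1.S 3.84-fold (1.94 ± 0.22) up and col9a1.L 2.31-fold (-1.21 ± 0.10) down.

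Marker lists of other tissues stood as follows at 48 h. In the skeletal muscle list 0 of 27 measured genes rose and 25 fell (0 and 26 adjusted over the list alone). Its median was -0.99 against -0.98 for probes of like brightness (camera adjusted p = 3.23e-08, and adjusted p = 0.382 with an estimated correlation), and -0.48 from the sample channel alone. In the intestine list 0 of 12 measured genes rose and 11 fell (0 and 11 adjusted over the list alone). Its median was -0.96 against -0.99 (camera adjusted p = 8.92e-05, and adjusted p = 0.227 with an estimated correlation). The neural and glial list had 2 of 26 measured genes higher and 19 lower (2 and 19 adjusted over the list alone). Its median was -0.50 against -0.68 (camera adjusted p = 0.000382, and adjusted p = 0.427 with an estimated correlation). Liver markers went both ways, with 3 up and 10 down of 42 (camera adjusted p = 0.113). The enzyme agxt.L fell, and the plasma protein genes ahsg.L 7.74-fold (2.95 ± 0.28) and f10.L 5.15-fold (2.36 ± 0.29) rose. The stomach and lung foregut (2 up and 7 down of 12), smooth muscle and stroma (7 up and 5 down of 19), endothelium (6 up and 1 down of 13), leukocyte (2 up and 9 down of 25), erythroid (4 up and 1 down of 17), adipose (3 up and 2 down of 11), antigen presentation (2 up and 1 down of 12), duct and progenitor (8 up and 4 down of 20) and oocyte (2 up and 7 down of 18) lists were not called, at camera adjusted p of 0.0874, 0.742, 0.306, 0.0826, 0.526, 0.937, 0.526, 0.526 and 0.187.

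**Figure D1:**
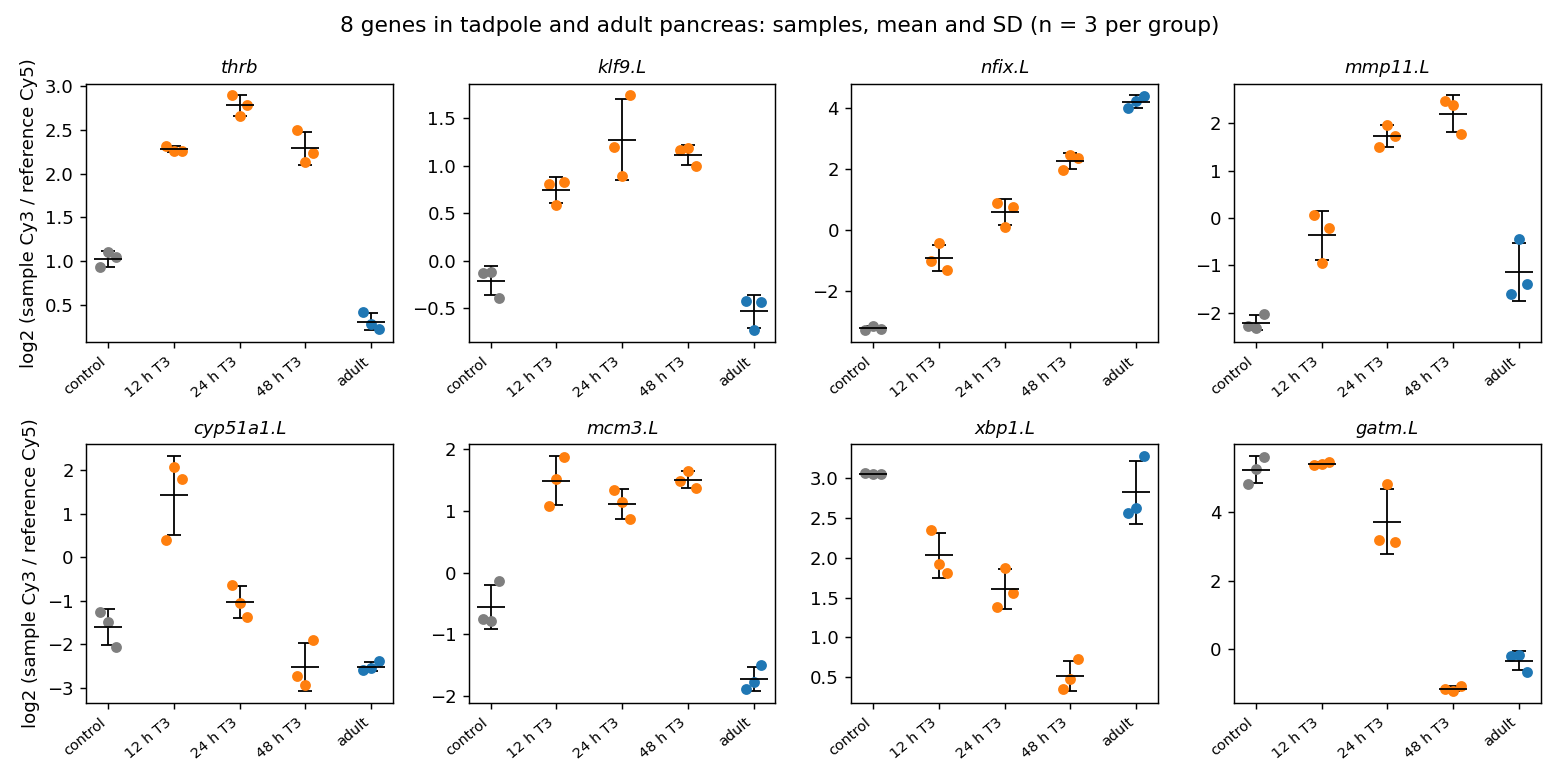
Log2 ratio of sample (Cy3) to reference (Cy5) for 8 genes in the 3 samples of each group (points), with the group mean and SD (bars). The gene thrb stood highest at 24 h of T3, nfix.L rose from control through 48 h to adult, cyp51a1.L peaked at 12 h, and gatm.L was at its lowest at 48 h.

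Of the 22001 probes, 10480 differed from control at 48 h, 4847 higher and 5633 lower, and 2382 by at least 2-fold (1059 higher, 1323 lower). The count was 10632 with the slide as a block in the tadpole samples and 10040 with it over all 16 arrays. On slides 1, 2 and 3, 99.7%, 99.9% and 99.7% of the called probes had the sign of the fit. These slides also gave the calls, so that agreement was largely fixed in advance. Median centring gave 9795 probes, 84.1% of them higher, against 46.3%. The camera call was lost with median centring for the matrix proteases and inhibitors (adjusted p = 0.0771) and endocrine pancreas (adjusted p = 0.0771) lists, from the sample channel alone for digestive enzymes (adjusted p = 0.541), and with the processed signals for the neural and glial list (adjusted p = 0.354). For digestive enzymes the quantile normalization of that channel can itself remove the call.

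Adult pancreas was compared with control tadpole pancreas to find what differs between the larval and the adult organ. The groups differed in methimazole and RNA handling as well as in age, and all adults were female. Digestive enzyme genes differed in opposite directions and by large factors. The elastases cela3b.L and cela3a.S were higher by 14.65 ± 0.67 (adjusted p = 1.89e-09) and 12.32 ± 0.34 on the log2 scale. The elastase cela1.2.L 133-fold (7.06 ± 0.35) and the trypsin prss1.2.S 52.3-fold (5.71 ± 0.94) were higher too. So was the bile salt lipase cel.1.S, by 6.60 on the log2 scale (limma adjusted p = 1.16e-07). The carboxypeptidase cpa1.S 9.66-fold (3.27 ± 0.12) and the amylase amy2a.L 2.86-fold (1.51 ± 0.24) had smaller rises in the ratio. The bile salt lipases cel.2.S and cel.2.L were lower, at -10.43 ± 0.24 (adjusted p = 2.24e-12) and -6.20 ± 0.16. The trypsin prss2.L was at -6.22 ± 0.51, and the elastases cela1.1.L 8.27-fold (-3.05 ± 0.35) and cela1.1.S 6.3-fold (-2.66 ± 0.38) fell as well. In the digestive enzymes list 12 of 20 measured genes were higher and 6 lower (13 and 6 adjusted over the list alone), 11 of them higher and 5 lower by over 1 on the log2 scale. Camera, which tests for a shift of the whole list, gave adjusted p = 0.0667. The reference signal at these probes also differed between arrays, although the reference RNA was the same. In 13 of the 18 called enzymes it went in the direction opposite to the ratio (cela3b.L -2.52, cel.2.S 1.34). In the others it went with the ratio, as at prss1.2.S (3.80) and cel.1.S (2.93), so sizes there are uncertain too. From the sample channel alone cela3b.L changed by 10.82, cela3a.S by 10.22, cel.2.S by -9.14, cpa1.S by 0.73 and amy2a.L by 0.083. Quantile normalization of that channel can hide a shared rise of the brightest probes. Before normalization their share of its signal was 62.4% to 65.3% in adult, against 52.8% to 56.3% in control. In that channel 17 of the 18 kept their sign, and 7 were higher and 5 lower by over 1. Array probes of near-identical paralogs can share signal, so the split between paralogs is uncertain. Islet genes were higher. In the endocrine pancreas list 17 of 22 measured genes were higher and 2 lower (17 and 3 adjusted over the list alone). Its median was 1.22 against -0.35 for probes of like brightness (camera adjusted p = 3.74e-05, and adjusted p = 0.51 with an estimated correlation). Examples were ins.S 2.92-fold (1.55 ± 0.16), gcg.L 3.48-fold (1.80 ± 0.19), and the somatostatin gene sst.1.L 8.98-fold (3.17 ± 0.26). Further ones were scg5.L 5.68-fold (2.51 ± 0.14) and neurod1.S 3.63-fold (1.86 ± 0.15). The acinar factor ptf1a.L 2.28-fold (1.19 ± 0.11) was higher. The acinar regulators and secretory markers list had 4 up and 3 down of 10 (camera adjusted p = 0.657).

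**Figure D2:**
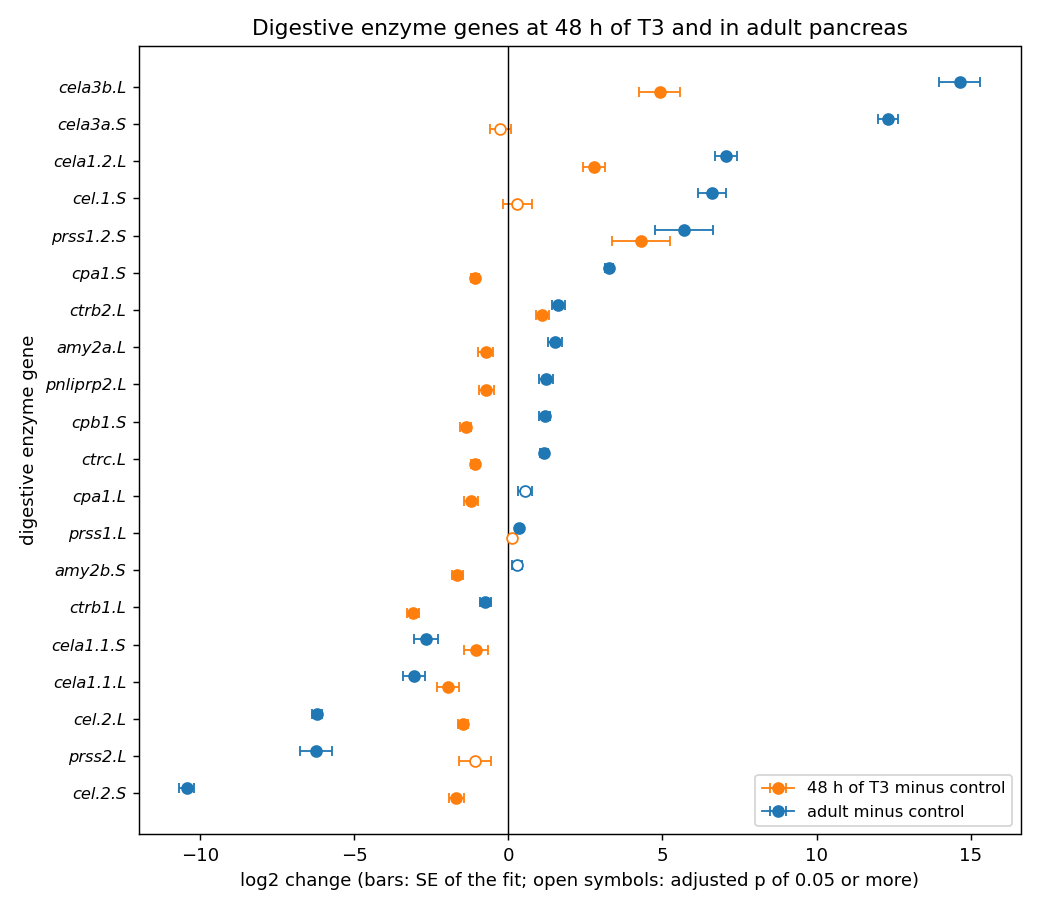
Log2 change of the 20 measured digestive enzyme genes at 48 h of T3 (orange) and in adult (blue) against control, with the SE of the fit as bars and open symbols for changes that did not pass an adjusted p of 0.05. In adult 12 genes were higher and 6 lower, and at 48 h 4 were higher and 12 lower.

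Other genes far above control in adult were ak6.S 244-fold (7.93 ± 0.15), an adenylate kinase, and nfkb2.S 173-fold (7.44 ± 0.14), a subunit of the NF-kappaB factor. So was nfix.L 169.7-fold (7.41 ± 0.23, adjusted p = 2.66e-11), which T3 had also raised. Genes far below were gatm.L 47.4-fold (-5.57 ± 0.34) and the globin hba4.S 91.8-fold (-6.52 ± 0.29). The gene nanos1.L, whose probe is named XCAT2 and described as a calcium transporter in the array's annotation, was lower by at least 141-fold and was not well above background in any adult sample. Among globins hbe1.L 19.5-fold (-4.28 ± 0.19), hbd.S 23.7-fold (-4.57 ± 0.24), annotated as larval, and hba2.L 37.6-fold (-5.23 ± 0.31) were lower. The erythroid list had 3 of 17 measured genes higher and 9 lower (3 and 9 adjusted over the list alone, camera adjusted p = 0.0215, and adjusted p = 0.591 with an estimated correlation). Collagens and matrix genes had 17 of 31 measured genes higher and 3 lower (19 and 4 adjusted over the list alone). Their median was 0.45, against 0.53 for probes of like brightness (camera adjusted p = 0.000476, and adjusted p = 0.51 with an estimated correlation). Examples were dcn.L 15.1-fold (3.92 ± 0.20), col1a1.S 11.7-fold (3.55 ± 0.14) and col3a1.S 10-fold (3.32 ± 0.18). The smooth muscle and stroma list had 14 of 19 measured genes higher and 0 lower (14 and 0 adjusted over the list alone). Its median was 0.73 against 0.26 (camera adjusted p = 0.00153, and adjusted p = 0.591 with an estimated correlation). An example was acta2.L 7.46-fold (2.90 ± 0.27). In the duct and progenitor list krt19.S 12.6-fold (3.66 ± 0.23) rose, sox9.L fell (-0.59 ± 0.15), and the list was not called (5 up and 6 down of 20; camera adjusted p = 0.962).

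Cell cycle and secretory pathway genes were lower in adult. In the cell cycle list 2 of 90 measured genes rose and 63 fell (2 and 67 adjusted over the list alone). Its median was -0.73 against -0.012 for probes of like brightness (camera adjusted p = 1.68e-10, and adjusted p = 0.564 with an estimated correlation). Examples were the proliferation marker mki67 4.86-fold (-2.28 ± 0.15) and cdc20.L 3-fold (-1.58 ± 0.14). The endoplasmic reticulum list had 4 of 77 measured genes higher and 48 lower (4 and 48 adjusted over the list alone). Its median was -0.74 against -0.21 (camera adjusted p = 1.82e-08, and adjusted p = 0.51 with an estimated correlation). Examples were hyou1.S 16.5-fold (-4.04 ± 0.34), sec62.L 10.8-fold (-3.44 ± 0.093) and pdia6.S 5.18-fold (-2.37 ± 0.17). In the oxidative phosphorylation list 2 of 46 measured genes rose and 28 fell (2 and 28 adjusted over the list alone, camera adjusted p = 5.13e-06, and adjusted p = 0.51 with an estimated correlation). An example was uqcrc2.S 2.51-fold (-1.33 ± 0.080). In the amino acid synthesis and tRNA charging list 4 of 31 measured genes rose and 17 fell (4 and 18 adjusted over the list alone, camera adjusted p = 0.00153, and adjusted p = 0.591 with an estimated correlation). Examples were nars1.L 5.28-fold (-2.40 ± 0.17) and cth.L 6.88-fold (-2.78 ± 0.29) down and cbs.S 2.73-fold (1.45 ± 0.17) up. The direct thyroid hormone response list was not called (7 up and 6 down of 20; camera adjusted p = 0.962). The receptor gene thrb was at -0.72 ± 0.097 (adjusted p = 4.33e-05) and klf9.L at -0.32 ± 0.17 (adjusted p = 0.148). The gene dio3.L was lower by at least 2.08-fold, and mmp11.L was higher by at least 2-fold. The matrix proteases and inhibitors list had 12 of 26 measured genes higher and 3 lower (13 and 3 adjusted over the list alone). Its median was 0.34 against 0.34 (camera adjusted p = 0.0484, and adjusted p = 0.591 with an estimated correlation).

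Markers of muscle, nerve and oocyte were higher in adult. The skeletal muscle list had 20 of 27 measured genes higher and 0 lower (20 and 0 adjusted over the list alone). Its median was 0.75 against 0.71 for probes of like brightness (camera adjusted p = 1.69e-05, and adjusted p = 0.58 with an estimated correlation). Examples were the troponin tnnt1.S 29-fold (4.86 ± 0.22) and the calcium pump atp2a1.S 7.68-fold (2.94 ± 0.23). The neural and glial list had 20 of 26 measured genes higher and 0 lower (20 and 0 adjusted over the list alone). Its median was 0.71 against 0.58 (camera adjusted p = 1.27e-05, and adjusted p = 0.51 with an estimated correlation). The oocyte list had 13 of 18 measured genes higher and 1 lower (13 and 1 adjusted over the list alone). Its median was 0.62 against 0.12 (camera adjusted p = 0.0050, and adjusted p = 0.199 with an estimated correlation). Examples were lsm14b.L 3.71-fold (1.89 ± 0.19) and wee2.L 3.18-fold (1.67 ± 0.18). Ribosomal proteins were not called (13 up and 3 down of 61; median 0.16 against 0.21; camera adjusted p = 0.128). Nor were the intestine (8 up and 1 down of 12; median 0.70 against 0.68; camera adjusted p = 0.141), liver (11 up and 6 down of 42; camera adjusted p = 0.762), leukocyte (4 up and 8 down of 25; camera adjusted p = 0.485) and immediate early and heat shock (10 up and 6 down of 30; camera adjusted p = 0.404) lists.

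**Figure D3:**
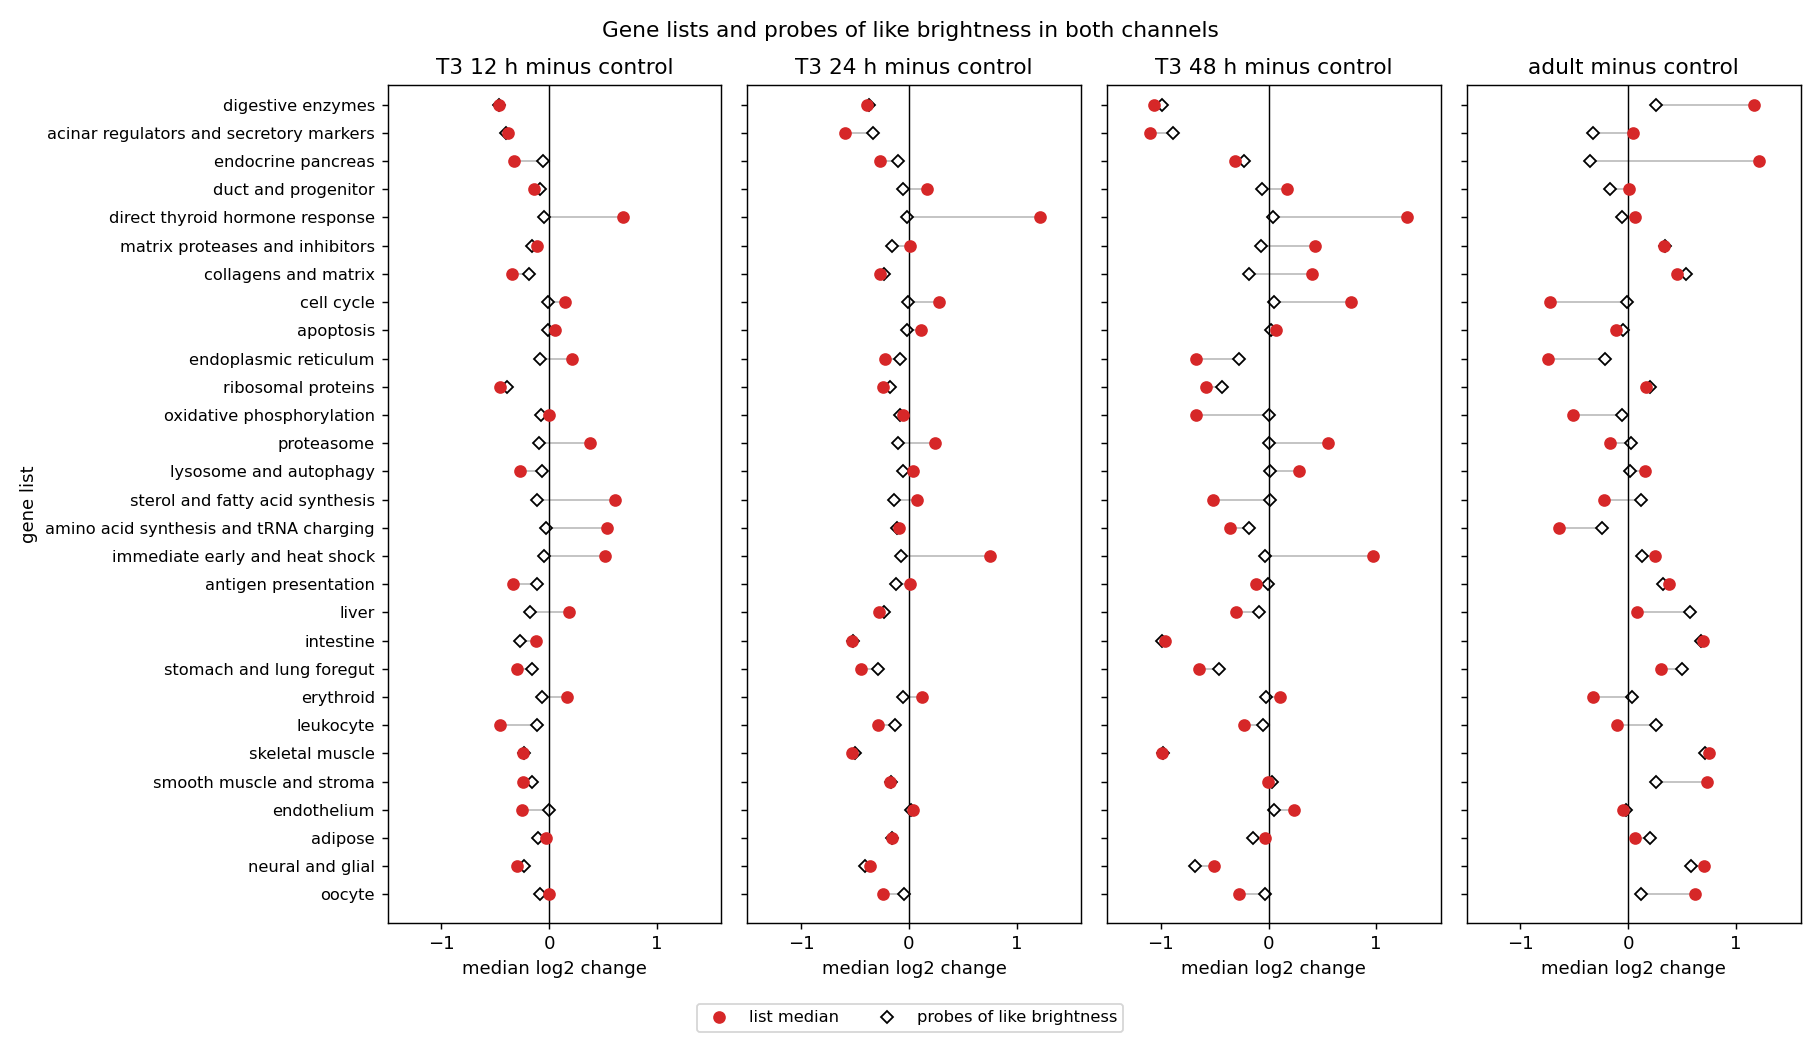
Median log2 change of each gene list (filled circles) and of other probes with like brightness in both channels (open diamonds), for the 4 comparisons with control. The skeletal muscle, intestine and neural and glial lists lie within 0.176 of their diamonds at 48 h and in adult, while the thyroid hormone response and cell cycle lists at 48 h and the endocrine list in adult lie far from theirs.

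In adult, 10405 probes differed from control, 5535 higher and 4870 lower, and 2500 by at least 2-fold (1188 higher, 1312 lower). All adult samples lay on slide 4, where the only control was the repeat array of pool 1. Against that array alone 99.6% of the called probes kept their sign. The adult arrays and that array also entered the calls, so this agreement was largely fixed in advance. With the slide as a block over the 16 arrays the count was 6790, and mmp11.L at adult stage (adjusted p = 0.118) and sox9.L at adult stage (adjusted p = 0.0554) did not pass. The share higher was 53.2%, and 27.5% with median centring. The camera call was lost with median centring for the erythroid list (adjusted p = 0.0656) and with the processed signals for the matrix proteases and inhibitors list (adjusted p = 0.11).

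Direct contrasts between times tested which effects differed. From 12 h to 24 h the sterol and fatty acid synthesis list fell, with 1 of 28 measured genes higher and 11 lower (2 and 17 adjusted over the list alone). Its median was -0.79 (camera adjusted p = 5.66e-08, and adjusted p = 0.345 with an estimated correlation). Also lower were the amino acid synthesis and tRNA charging list (0 up and 12 down of 31; median -0.61; camera adjusted p = 3.2e-08, and adjusted p = 0.345 with an estimated correlation) and the endoplasmic reticulum list (1 up and 19 down of 77; median -0.42; camera adjusted p = 4.77e-08, and adjusted p = 0.345 with an estimated correlation). The direct thyroid hormone response list rose further (7 up and 1 down of 20; median 0.52; camera adjusted p = 0.00136, and adjusted p = 0.345 with an estimated correlation), with mmp11.L 2.10 ± 0.30 and thrb 0.50 ± 0.097 higher on the log2 scale. From 24 h to 48 h the cell cycle list rose (46 up and 2 down of 90; median 0.49; camera adjusted p = 4.92e-09, and adjusted p = 0.473 with an estimated correlation). The oxidative phosphorylation list fell (0 up and 34 down of 46; median -0.62; camera adjusted p = 9.08e-17, and adjusted p = 0.145 with an estimated correlation). So did the endoplasmic reticulum (5 up and 33 down of 77; median -0.42; camera adjusted p = 7.15e-09, and adjusted p = 0.392 with an estimated correlation) and digestive enzymes (1 up and 9 down of 20; median -0.54 against -0.57 for probes of like brightness; camera adjusted p = 0.00355, and adjusted p = 0.442 with an estimated correlation) lists. Over the same interval ctrb1.L changed by -2.54 ± 0.19, ins.S by -0.61 ± 0.16 and gcg.L by -0.84 ± 0.19, and thrb changed by -0.49 ± 0.097.

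Between 12 h and 24 h 1535 probes differed, 728 higher and 807 lower, and 212 by at least 2-fold (77 higher, 135 lower). The count was 1330 with the slide as a block in the tadpole samples, 1198 with it over all 16 arrays and 455 (84.6% higher, against 47.4%) with median centring. It fell to 781 and 855 without 12 h replicates 2 and 3 and to 811 and 934 without 24 h replicates 1 and 3. Between 24 h and 48 h 5374 probes differed, 2792 higher and 2582 lower, 609 by at least 2-fold (246 higher, 363 lower). That count was 5443 with the slide as a block in the tadpole samples and 4905 with it over all 16 arrays, and the share higher was 52.0%, against 81.5% with median centring and 39.7% without the offset in the background step. From the sample channel alone the camera call of digestive enzymes between 24 h and 48 h was lost (adjusted p = 0.359). Quantile normalization of that channel can hide a shared fall of the brightest probes. Before normalization their share of its signal was 46.7% to 51.3% at 24 h and 39.4% to 40.4% at 48 h.

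Adult pancreas was set against the pancreas after 48 h of T3 to see how far the treated larval organ stood from the adult one. In all 13900 probes differed, 7339 higher and 6561 lower in adult, 5061 by at least 2-fold. Cell cycle genes were lower in adult (1 up and 84 down of 90; median -1.67; camera adjusted p = 5.32e-15, and adjusted p = 0.309 with an estimated correlation). So were proteasome genes (7 up and 29 down of 46; median -0.71; camera adjusted p = 0.00066, and adjusted p = 0.309 with an estimated correlation) and the direct thyroid hormone response list (5 up and 14 down of 20; median -0.99; camera adjusted p = 0.0136, and adjusted p = 0.309 with an estimated correlation). Endocrine genes were higher (18 up and 2 down of 22; median 1.79; camera adjusted p = 2.98e-05, and adjusted p = 0.339 with an estimated correlation). So were digestive enzymes (13 up and 5 down of 20; median 1.93 against 1.01 for probes of like brightness; camera adjusted p = 0.0113, and adjusted p = 0.395 with an estimated correlation), acinar regulators (9 up and 1 down of 10; median 1.34; camera adjusted p = 0.00277, and adjusted p = 0.309 with an estimated correlation) and skeletal muscle genes (26 up and 0 down of 27; median 1.74 against 1.69 for probes of like brightness; camera adjusted p = 3.54e-09, and adjusted p = 0.309 with an estimated correlation). With median centring the median of acinar regulators was -0.078, where all probes had a median of -0.243. These groups lay on different slides, with control pool 1 as the link between them. They differed in methimazole and RNA handling too. With the slide as a block over the 16 arrays the count was 8950, below the 10040 of 48 h against control in that fit. The share higher was 52.8%, against 24.5% with median centring. The camera call was lost with median centring for the direct thyroid hormone response list (adjusted p = 0.218) and from the sample channel alone for digestive enzymes (adjusted p = 0.199). For digestive enzymes the quantile normalization of that channel can itself remove the call.

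The changes from control at 48 h and in adult were weakly correlated across probes. Their log2 changes correlated at r = 0.057 over 22001 probes, which are not independent replicates, with a covariance of 0.0285. Groups simulated without any change that shared chance values of 3 controls gave covariances of 0.0122 to 0.0146 and correlations of 0.468 to 0.528. The observed covariance was above the simulated one. The correlation was below it, which says nothing, since any real change lowers a correlation that shared controls alone produce. The simulation drew noise separately for each probe, so its range may be too narrow. With no control pool in common the observed covariance ran from -0.0194 to 0.0559. With median centring the covariance turned to -0.0468. Of the 6018 probes called in both comparisons 2502 (41.6%) moved the same way and 3516 the opposite way. Probes higher in both numbered 952, where independent lists of these sizes would share 1219, and probes lower in both 1550, against 1247. Probes raised at 48 h and lower in adult numbered 1431 against 1073, and those lower at 48 h and higher in adult 2085 against 1417. In 101 bright reference probes not well above background in Cy3 on any array, the median change was -0.52 at 48 h and 0.41 in adult. Whether such a shift at dim probes added to the last excess was not tested. The gene nfix.L was higher than control at 48 h (5.46 ± 0.23) and further in adult (7.41 ± 0.23).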

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

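The tests of slide 4, of the share of acinar tissue, of the reference brightness, of tissue amounts, of time of day and of shared controls were chosen after the results were seen.

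T3 effects that differed between times, by a test of the difference itself, stand out first. Between 12 h and 24 h 1535 probes differed (limma), and between 24 h and 48 h 5374. Lists called higher at 24 h than at 12 h (camera) had medians of direct thyroid hormone response 0.52, matrix proteases and inhibitors 0.18, ribosomal proteins 0.20, lysosome and autophagy 0.25, immediate early and heat shock 0.37 and endothelium 0.30. With an estimated correlation camera called 0 of the 29 lists in either contrast between times. Lists called lower had medians of acinar regulators and secretory markers -0.32, endoplasmic reticulum -0.42, sterol and fatty acid synthesis -0.79, amino acid synthesis and tRNA charging -0.61, liver -0.32, intestine -0.40 and skeletal muscle -0.26. From 24 h to 48 h the rising lists were matrix proteases and inhibitors 0.45, collagens and matrix 0.44, cell cycle 0.49 and lysosome and autophagy 0.21. The falling lists were digestive enzymes -0.54, acinar regulators and secretory markers -0.40, endoplasmic reticulum -0.42, ribosomal proteins -0.33, oxidative phosphorylation -0.62, amino acid synthesis and tRNA charging -0.53, intestine -0.52, skeletal muscle -0.44 and neural and glial -0.22. The last of these medians came to 0.023 from the sample channel alone. From 24 h to 48 h probes of like brightness had medians of -0.57, -0.52, -0.46, -0.44 and -0.28 beside the digestive, acinar, intestine, skeletal muscle and neural lists. Among the genes followed whatever their values, those higher at 24 h than at 12 h were thrb.S 0.56, cela1.2.L 2.08, thrb 0.50, thibz.L 0.60 and mmp11.L 2.10. The gene dio3.L was lower, at -0.57. From 24 h to 48 h dio3.S was higher, at 0.99. Lower ones were thrb.S -0.39, cela1.1.L -1.53, ins.L -1.22, ins.S -0.61, thrb -0.49, cpa1.L -0.89, cpa1.S -0.49, ptf1a.L -0.41, ctrb1.L -2.54 and gcg.L -0.84. Of 232 other named genes tested, 70 differed from 12 h to 24 h and 124 from 24 h to 48 h. Groups of 3 samples are too small for a test of outlying samples.

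In adult, digestive enzyme paralogs changed in opposite directions, 11 higher and 5 lower by over 1 on the log2 scale, with sizes that depend on the channels and normalization used (cela3b.L 14.65, and 10.82 from the sample channel alone). Slide 4 did not account for this, since the repeat control array there differed from the slide 1 array of the same RNA with a slope of only 0.0139 on the adult change. A different share of acinar tissue would move these genes one way, and 5 called genes lay past 1 in the smaller direction. Handling stays open, because the 18 of 18 called enzymes that kept their sign against the repeat array in 3 of 3 adult samples share the adult handling. A larval and an adult set of paralogs may account for the pattern. This hypothesis cannot be told apart here from handling, or from methimazole, which all tadpoles had and no adult had. All adults were female, so sex stays open too.

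The skeletal muscle, intestine and neural lists fell at 48 h and had higher medians in adult, in step with probes of like brightness. The median of such probes was at least 0.823 of the list median in each of 6 values, so a reference far brighter than the sample is a candidate source. In 101 bright reference probes not well above background in Cy3 on any array, the median change was -0.52 at 48 h and 0.41 in adult. Different amounts of muscle, gut or nerve tissue cannot be told apart from this, with a largest gap of 0.176, because probes bright in the reference and dim in pancreas can be genes of those tissues. No biological explanation was tested.

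Sterol synthesis genes rose at 12 h and were lower at 24 h than at 12 h (median -0.79). The slide did not account for the rise, with 0.248 as the lowest of the 3 within-slide medians. Position on the slide went with the group, so these medians cannot decide on it and it stays open. Within slides 1, 2 and 3 the sterol list had medians of 0.25, 1.2 and 0.69 at 12 h. The liver list followed the same order, at -0.16, 0.62 and 0.44. Different amounts of liver tissue in the pools were not tested and stay open. Time of day stays open: 11 clock genes had a median absolute change of 0.145 from 12 h to 24 h, but nr1d1.L, the 1 that was called, changed by -2.06. Time in the bath stays open too, with no control at 12 h and a list median of 0.0778 against control at 24 h. A transient effect of T3 may account for the pattern and cannot be told apart from these.

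Of the 10 splits of the 6 samples, 1, the real one, called as many probes in each of the 7 contrasts, and 10 splits are too few for a share under 0.05. The highest other split called 1 probe at 12 h (4544 in the real split), 1 at 24 h (5184), 0 at 48 h (10480), 1 in adult (10405) and 0 between adult and 48 h (13900). It called 20 between 12 h and 24 h (1535) and 0 between 24 h and 48 h (5374). Among the 4 splits that part all 3 slides, the highest other called 0, 1 and 0 at 12 h, 24 h and 48 h, and 1 and 0 between times. The remaining splits part 1 slide. Every split but the real one mixes samples of both groups, so a real difference widens the spread within groups. Low counts there are thus largely built in and do not show what unchanged groups would call.

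The covariance of the 48 h and adult changes was 0.0285, against 0.0122 to 0.0146 in simulated unchanged groups and -0.0468 with median centring. The simulation drew noise separately for each probe, so its range may be too narrow. Part of the excess may come from the shared controls, since 3 pools cannot be split with 2 on each side. In the 6 ways to give 1 pool to one comparison and the other 2 to the other, the covariance ran from -0.0194 to 0.0559, so single pools settle nothing, and the source of the excess stays open.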

How the results depend on the processing

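The slides 1 to 3, repeat array, Cy3-alone correlation, split-control, list normalization, like-brightness, single-channel and list block settings were chosen after the data were examined. Over the alternatives, genes named by the rule gave 14474 values, of which 13495 kept their direction and side of the threshold, 850 lost the call, 98 gained it and 31 turned, 3 of them for genes described in the text and given next. For lists, by the direction camera gave and not the sign of the median, these were 1782 of 1972, 157, 33 and 0. Some list medians did change sign, as given with the comparisons. Of 182 probe counts 160 stayed within 1.5 times. These tallies count settings that could not differ from the main fit: Aquantile, and for genes and probe counts the saturation filter. They also count the value table beside the processed signals, which nearly repeat each other (3222 and 3228 probes at 12 h). Where no construction is named, the cause was not tested.

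A 2-fold minimum left 528, 638 and 2382 probes at 12 h, 24 h and 48 h, 2500 in adult, 5061 between adult and 48 h, and 212 and 609 between successive times. With median centring 1558 probes were called at 12 h and 455 between 12 h and 24 h. That last count was 673 with the processed signals, 668 with the value table, 812 without the offset and 649 from its 2 groups alone, a fit on fewer samples. Without 1 replicate it ran from 781 to 1688, lowest without 12 h replicate 2, and the 12 h count from 2821 to 4464, lowest without control replicate 2. With the slide as a block over 16 arrays, which leaves 1 control array beside the adults, 6790 probes differed in adult and 8950 between adult and 48 h, and against the repeat array alone 6885 in adult. From the sample channel alone amy2a.L at 48 h came to 0.14 and ptf1a.L at 48 h to 0.13, and with median centring ptf1a.L came to 0.45. The correlation of 48 h and adult changes was -0.0991 with median centring, 0.0572 with the processed signals, 0.0538 without the filter, 0.072 from Cy3 alone and 0.0754 with the repeat array as the adult control. With no control pool in common it was 0.0573, 0.0821 and -0.0275 with pool 1, 2 or 3 alone for adult, and 0.0327, -0.0358 and 0.115 with pool 1, 2 or 3 alone for 48 h. With an estimated correlation, camera called 0 lists at 12 h, 0 at 24 h, 0 at 48 h, 0 in adult, 0 between adult and 48 h, and 0 and 0 between times.

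The replicate number as a block (paired samples) gave 4499, 5126 and 10632 probes at 12 h, 24 h and 48 h. In adult, where the number pairs nothing, it gave 10124. Besides the calls given with the comparisons it added cela1.1.S at 12 h (adjusted p = 0.03), ctrb1.L at 24 h (adjusted p = 0.0109), the endoplasmic reticulum list, 24 h (adjusted p = 0.037), the apoptosis list, 24 h vs 12 h (adjusted p = 0.0484) and the smooth muscle and stroma list, 48 h vs 24 h (adjusted p = 0.0472), and it changed no other call of a named gene against control or of a list. Over all probes 3967 of the 4544 called at 12 h, 4556 of the 5184 at 24 h and 10010 of the 10480 at 48 h stayed called. Aquantile leaves log ratios as they are and no probe was saturated, so these settings say nothing. The slide 4 arrays, with the higher background, had the fewest probes well above it, which limits dim genes in adult.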

Other observations

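The genes given here were chosen after the values were seen. Of 11 measured genes of the circadian clock, 5, 6 and 7 were lower than control at 12, 24 and 48 h of T3 and 0 higher (limma). The repressor nr1d1.L was at -0.16 ± 0.23 at 12 h, which did not pass the test, -2.22 ± 0.23 at 24 h and -2.47 ± 0.23 at 48 h. The cryptochrome cry2.L fell at all 3 times, by log2 changes of -0.98 ± 0.21, -1.32 ± 0.21 and -1.69 ± 0.21. So did the period gene per1.L, with -0.68 ± 0.18, -0.68 ± 0.18 and -1.0 ± 0.18. Control and 48 h samples were collected together. In adult 4 clock genes were higher and 4 lower, with cry2.L at 1.51 ± 0.21 and cry1.L at -2.50 ± 0.21.

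Leptin (lep.S), a hormone of adipose tissue, and vitellogenin (vtgb1.L), the yolk precursor made in the liver of females, were not well above background in control. In the adult frogs, which were female, lep.S was at least 4.45-fold and vtgb1.L at least 96.5-fold higher. The 3 adult samples differed widely in vtgb1.L, with an SD of 2.46 on the log2 scale. The adipose list, with 3 up and 3 down of 11 in adult, was not called (camera adjusted p = 0.657).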
